A study of Mus musculus with 6 samples.

How the data were processed

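Single-cell RNA was measured in sciatic nerve cells of 23-week-old C57BL6/J mice kept on a standard diet (SD) or a high fat diet (HFD). Schwann cells had been enriched with magnetic beads against O4, a surface lipid antigen of the oligodendrocyte and Schwann lineages, and libraries were made with the droplet-based 10x Genomics 3' chemistry, per the labels' protocols. Reads were processed with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. The authors deposited raw UMI counts (counts of distinct molecules) for 32285 gene symbols in 364 cell barcodes, a table with the library, cluster number and cluster name of each barcode, and a key of library names. The filters on cells and the doublet treatment that preceded deposit are not given in the sources used here. No doublet caller was run on the 364 cells. The share of UMIs from mitochondrial genes, as a percent per cell, is in the deposited table and lay under 5 in each cell (highest recomputed value 4.97%).

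The labels name 3 SD and 3 HFD samples. The control libraries of the deposited tables were taken as SD, because the tables and the labels each hold 2 diets and share the name HFD. Cells were present for 5 libraries, and HFD replicate 3 was not analysed here. All 5 library names matched a sample, and 0 did not. The folder names in the library key carry 2 project numbers, taken here as sequencing runs. Run 1 held SD replicates 1 and 2 and HFD replicate 1, and run 2 held SD replicate 3 and HFD replicate 2. Nothing in the labels says that samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

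Counts were summed per library over all cells, and per library and deposited cluster. The sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit with the diet as the only term) with Benjamini-Hochberg adjustment at 0.05. CPM from these fits are TMM-normalized and taken over the UMIs of the genes kept by filterByExpr alone. CPM of marker genes and lists per cluster divide their UMIs by all UMIs of the cluster in that library, without TMM scaling. Pooled CPM likewise use all UMIs. Values from fits can therefore lie higher and are not comparable with the others. In cluster 4 of SD replicate 1, Dcn was at 31138 CPM from the fit and 10801 over all UMIs. Values after ± are standard deviations between libraries, except beside log2 fold changes. Standard errors of log2 fold changes were derived as the fold change divided by the square root of the F statistic and are approximate. A cluster was tested where at least 2 libraries per diet held at least 10 of its cells, which cluster 0 alone met, in 2 SD and 2 HFD libraries. Clusters 1, 2 and 4 were tested with at least 3 cells per library, a minimum chosen after seeing the data. The planned test of diet by cluster met its minimum of 10 cells in no pair of clusters and was run for clusters 0 and 2 with at least 3. Of 24 pathway lists and 15 cell type lists, those with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the pathway lists and separately over the cell type lists. Cluster shares and depth per cell were compared with two-sided exact permutation tests of the difference in means (scipy 1.17.1). With 3 against 2 libraries there are 10 splits and the smallest p is 0.1.

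Genes were named by a rule. Over all cells these were the genes past the threshold with non-overlapping libraries, up to 12 per direction. In a cluster they were up to 4 per direction, or the 4 with the lowest p per direction where fewer than 3 passed. Mbp, Pmp22, Sox10 and S100b were among the Schwann genes always included, with up to 3 members of lowest p from each pathway list described. Not every gene that the rule selects is reported here. Unnamed gene models were counted and not named. The lists, tests, naming rule and most alternatives were fixed before the data were examined. Genes of clusters, single cells and barcodes described outside this rule were chosen after their values were seen.

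Total counts ranged from 37744 to 349450 UMIs per library and from 122 to 24932 per cell. The pipeline was tested on simulated counts drawn from the real library sizes, with 200 genes changed. Over all cells (5510 genes) edgeR recovered 0% of genes raised by 1 on the log2 scale, 16.1% of those raised by 2 and 78.8% of those raised by 3, and 0%, 32.1% and 30.4% of genes lowered by 1, 2 and 3. In cluster 0 (2108 genes) it recovered 91.4% of genes raised by 2 and 60% of those lowered by 2, and in cluster 2 (1019 genes) 82.1% and 45.7%. Calls among unchanged genes were 0.0409% over all cells, 0.109% in cluster 0 and 0.619% in cluster 2. Intervals of shares are exact 95% binomial intervals (confidence level 0.95), and intervals and floors (3 counts) cover counting error only. Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out cells with at least 2 UMIs of any non-Schwann marker list, equal weight per cell (log2 of mean CPM plus 10, limma), at least 20 cells per library, an adjusted p under 0.1, camera with an estimated correlation, fry, and leaving out each library. Added after seeing the data were the sequencing run as a term and leaving out cluster 0, barcodes with a shared ending, or cells with at least 10 UMIs of S100a8 and S100a9. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.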

Results

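The series asked how a high fat diet changes the transcriptome of Schwann cells, the glia of peripheral nerve. Counts were analysed for 364 cells in 5 libraries, 201 cells from 3 SD libraries and 163 cells from 2 HFD libraries. The SD libraries held 80, 81 and 40 cells with 296605, 154528 and 37744 UMIs. The HFD libraries held 57 and 106 cells with 349450 and 317297 UMIs. The median cell of a library had 1167 ± 1228 UMIs on SD (standard deviation, n = 3) and 3713 ± 4094 on HFD (standard deviation, n = 2), a difference within the spread between libraries (exact permutation p = 0.4, BH-adjusted 0.75). HFD replicate 1 was the deepest library, with a median of 6608 UMIs per cell, and without it the difference turned negative. Median genes per cell were 563 ± 552 on SD (n = 3) and 1143 ± 1009 on HFD (n = 2; exact permutation p = 0.5, BH-adjusted 0.75). The mitochondrial share of UMIs was 2.43% ± 0.283 (standard deviation, n = 3) and 2.44% ± 0.0607 (standard deviation, n = 2; exact permutation p = 1). Within run 1 the median UMI count per cell was 5022.5 higher on HFD, and within run 2 it was 488 higher.

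The deposited tables divided the cells into 5 clusters, and cluster 0 held macrophages by its leading genes. Its 143 cells, which the authors named Macrophages, carried all 15 members of the macrophage list, at 27237 ± 3139 CPM (standard deviation, n = 5 libraries). Apoe, a lipid carrier protein, reached 21341 ± 4005 CPM, the class II chaperone Cd74 16540 ± 4877, and the complement component C1qa 4311 ± 958 (n = 5). The myelinating Schwann list was at 703 ± 633 CPM in this cluster.

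Cluster 2 expressed the genes of myelinating Schwann cells. Its 60 cells, named SCP by the authors, carried 13 of 14 myelinating Schwann markers at 45929 ± 9426 CPM (standard deviation, n = 5). Pmp22, the peripheral myelin protein gene, was counted in 93.3% of the cells at 7146 ± 1874 CPM, and Prx, which encodes periaxin of the myelin sheath, in 96.7% at 1435 ± 370 (n = 5). In SD replicates 2 and 3 the list was higher in cluster 1, at 53388 and 68665 CPM against 45887 and 56836. Sox10, the transcription factor of the Schwann lineage, was at 476 ± 163 CPM. Ctnna3, an alpha-catenin gene, was counted in all 60 cells at 4554 ± 1372 CPM. The immature Schwann list was at 1190 ± 1074 CPM (n = 5), the highest mean of the 5 clusters, with 69% of its UMIs from Pou3f1. In SD replicates 1 and 3 that list was higher in cluster 1, at 553 and 1612 CPM against 308 and 723.

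Cluster 1, named mySC by the authors, held 92 mostly shallow cells with a median of 626.5 UMIs, against 4230 in cluster 2. Its median was 6340.5 in HFD replicate 1 and between 301 and 880 in the other libraries. Mbp, the myelin basic protein gene, was counted in 80.4% of them at 9914 ± 15774 CPM and Pmp22 in 69.6% at 6106 ± 4808 (standard deviation, n = 5). The 10 genes that led the cluster by fold came from few cells and were not Schwann genes. They comprised 4 haemoglobin genes and 4 mast cell protease or peptidase genes. In HFD replicate 1, 1 barcode held 9282 UMIs of Hbb-bs, 37.2% of its 24932 UMIs, and 1 SD replicate 1 barcode held all 90 UMIs of the mast cell protease Mcpt4.

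Clusters 3 and 4 were led by genes other than the Schwann markers of their names. Cluster 4, named nmSC by the authors, held 24 cells that expressed fibroblast genes at 42013 ± 21978 CPM (standard deviation, n = 4 libraries). The matrix proteoglycan Dcn alone reached 22653 ± 15347 CPM, against 370 ± 196 for the nonmyelinating Schwann list. Scn7a, of that list, was counted in 29.2% of the cells at 234 ± 212 CPM, the highest of the 5 clusters. Endothelial markers were at 2499 ± 2809 CPM in the same cluster. Cluster 3, named repairSC by the authors, held 45 cells with a median of 261 UMIs. Of the 14 nonmyelinating Schwann markers, Chl1, a neural adhesion gene, supplied 97.3% of the list's UMIs in cluster 3, and Scn7a had 0. The repair Schwann list was at 203 ± 183 CPM in cluster 3 (standard deviation, n = 3), below its level in cluster 0. In 36 of these 45 barcodes the last 9 bases were the same, and each of these 36 had between 128 and 531 UMIs. Because leading genes and names disagreed in several clusters, clusters are compared by number.

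**Figure D1:**
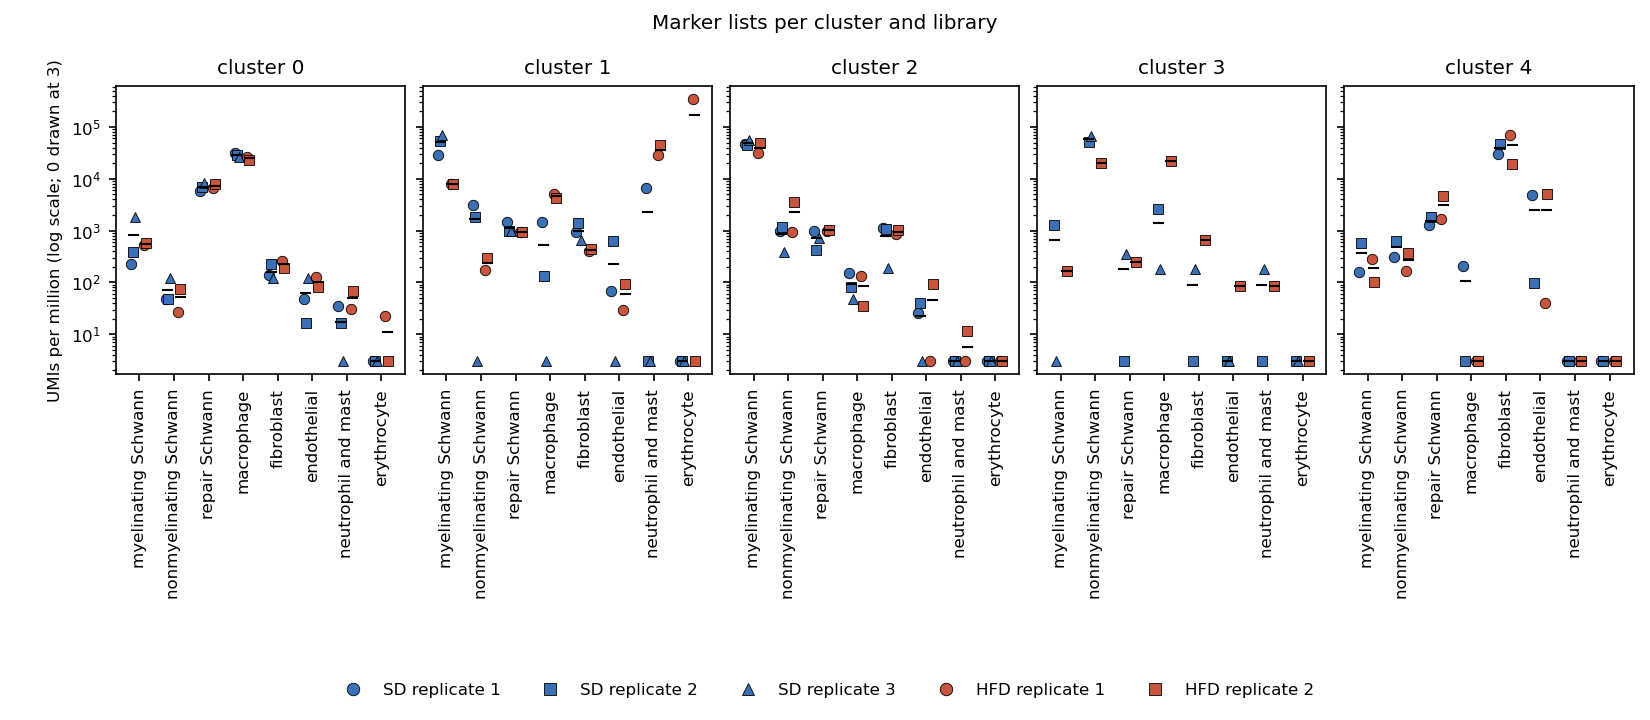
CPM of 8 marker lists (vertical axis, log scale, 0 drawn at 3) in each of the 5 clusters. Points are libraries with at least 3 cells of the cluster and bars are diet means; the macrophage list averages 27237 in cluster 0, the myelinating Schwann list 45929 in cluster 2 and the fibroblast list 42013 in cluster 4.

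Over all cells, 5 of 5510 tested genes differed between diets, and all 5 were neutrophil-type or stress genes counted in the HFD libraries with 0 UMIs in the SD libraries. S100a9 and S100a8, which encode the calprotectin subunits abundant in neutrophils, reached 6132 ± 3637 and 4027 ± 2258 CPM on HFD (standard deviation, n = 2). Pooled over the HFD libraries they were at 4972 and 3268 CPM, at least 810-fold and at least 533-fold above a floor of 3 counts in the pooled SD libraries. Without SD replicate 1, which holds most SD UMIs, these bounds fall to 319-fold and 209-fold, and those of the other 3 genes to between 12.5-fold and 46.5-fold. The neutrophil product Retnlg reached 884 ± 125 CPM (at least 118-fold higher), the cystine transporter Slc7a11 327 ± 239 (at least 43-fold) and the stefin Stfa2l1 239 ± 100 (at least 31.8-fold). Adjusted p-values in edgeR were 0.000578 for S100a9 and S100a8, 0.00345 for Retnlg, and 0.0428 for Slc7a11 and Stfa2l1. No gene was lower on HFD at the adjusted threshold, while 76 were lower and 166 higher at an unadjusted p under 0.05, and DESeq2 called 9 genes, all higher.

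These 5 genes came from very few cells. S100a9 was counted in 6 cells, and 5 of them held between 342 and 1015 of its UMIs each. These 5 neutrophil-like cells held 99.97% of the S100a9 UMIs, 99.8% of the Retnlg UMIs and 97.2% of the Slc7a11 UMIs. HFD replicate 1 held 4 of them, 7.02% of its cells, and HFD replicate 2 held 1, 0.943% of its cells. None was found among 201 SD cells, where a floor of 3 cells would be 1.49%. With these 5 cells left out, a setting chosen after seeing the data, 0 genes passed in edgeR and 197 had an unadjusted p under 0.05. Without SD replicate 1 the count also fell to 0, without HFD replicate 2 it was 54, and with the run as a term it was 57 (40 higher, 17 lower), the 5 genes among them.

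Myelin genes were lower on HFD as a group over all cells, without any single one passing. All 21 measured members of the myelin protein list lay below SD, with a median log2 fold change of -1.22 (camera adjusted p = 6.27e-11; adjusted p = 0.673 with an estimated correlation). Mbp was at 3431 ± 2595 CPM on SD (standard deviation, n = 3) and 701 ± 596 on HFD (n = 2), a log2 fold change of -2.28 ± 0.75 (SE; edgeR adjusted p = 0.943). Pmp22 was at 4425 ± 870 and 2121 ± 1400 (log2 -1.06 ± 0.47). Log2 fold changes were -1.43 ± 0.71 for Sox10 and -1.67 ± 0.64 for S100b, none past the threshold. Between 94.3% (Pmp22) and 100% (Sox10) of the UMIs of these 4 genes lay in clusters 1 and 2. Those clusters supplied 40.9%, 46.3% and 63.2% of UMIs in the SD libraries, and 23.8% and 41.2% in the HFD libraries. Without neutrophil-like cells and a haemoglobin-rich barcode, left out after seeing the data, the HFD shares were 15.5% and 40%. The log2 ratio of Mbp was -2.76 within run 1 and -2.50 within run 2. Those of Sox10 were -1.68 and -1.73, while those of Pmp22 were -1.92 and -0.574 and those of S100b -2.73 and -0.709. With the run as a term, Mbp (log2 -2.67) passed in edgeR.

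Cholesterol synthesis genes moved the same way. All 14 measured members lay below SD, with a median of -0.81 (camera adjusted p = 6.04e-05; adjusted p = 0.673 with an estimated correlation). The squalene synthase gene Fdft1 was at 108 ± 19.8 CPM on SD (n = 3) and 33.7 ± 31.7 on HFD (n = 2), and Hsd17b7, a sterol reductase gene, at 44.4 ± 19.6 and 7.15 ± 4.76. No member passed when adjusted over the list alone or over all genes tested. In cluster 2, 4 of 6 measured members lay below SD and 2 above. The list did not pass there (camera adjusted p = 0.161, and 0.546 with an estimated correlation). A change in cell mix was not separated from a change within cells.

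The pathway lists that passed in camera on the higher side over all cells, with the preset correlation alone, were antigen presentation, dissociation-induced immediate early and heat shock genes, cytokines and chemokines, and cytosolic ribosomal proteins. All 15 antigen presentation members were above SD (median 0.73, camera adjusted p = 0.00016; adjusted p = 0.673 with an estimated correlation). The costimulatory ligand gene Cd86 was at 105 ± 88.1 CPM on SD (n = 3) and 474 ± 105 on HFD (n = 2), and Ciita, the activator of class II genes, at 25.9 ± 4.84 and 85.6 ± 2.03. Of 26 immediate early and heat shock genes, 23 were above SD (median 0.89, camera adjusted p = 5.23e-06; adjusted p = 0.673 with an estimated correlation), among them Btg2 at 720 ± 105 and 1702 ± 47.5 CPM. Of 16 cytokine genes, 12 were above SD (camera adjusted p = 0.0289; adjusted p = 0.673 with an estimated correlation). Il34, a ligand of the macrophage receptor Csf1r, lay below SD at 126 ± 9.85 and 27.1 ± 6.26 CPM, not past the threshold. Ribosomal protein genes were above SD in 78 of 80 cases by a median of 0.34 (camera adjusted p = 0.0024; adjusted p = 0.783 with an estimated correlation). That ribosomal direction turned without cells carrying non-Schwann markers. By cluster, ribosomal protein genes lay below SD in 79 of 79 cases in cluster 0 and 61 of 78 in cluster 2. They lay above SD in 77 of 78 cases in cluster 1 and 47 of 75 in cluster 4. No member of these 4 lists passed when adjusted over the list alone or over all genes tested. The macrophage marker list was also higher (median 0.65 over 15 members, camera adjusted p = 0.0136, and 0.773 with an estimated correlation). Cluster 0 made up a mean of 28.6% of cells on SD and 54.9% on HFD. Inside it, antigen presentation genes were above SD in 8 of 13 cases. Immediate early and heat shock genes were above SD in 15 of 24, and cytokine genes in 9 of 10. None of these lists passed there (camera adjusted p = 0.505 each). With the preset correlation, antigen presentation passed in cluster 1 and the immediate early list in cluster 4. Cell mix and changes within cells were not separated.

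**Figure D2:**
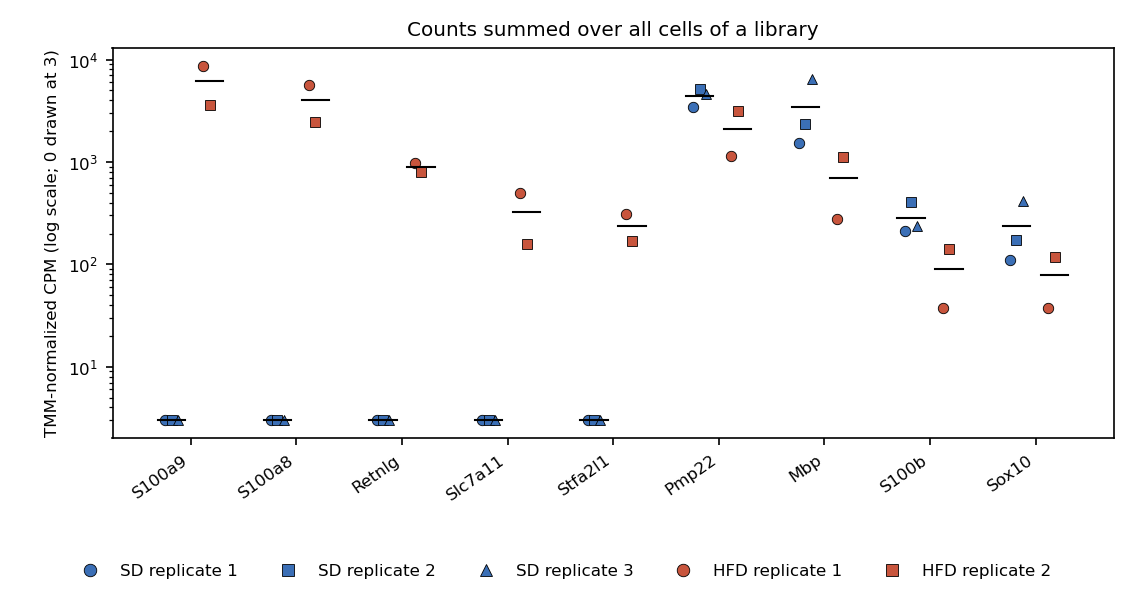
TMM-normalized CPM (vertical axis, log scale, 0 drawn at 3) of the 5 genes past the threshold and 4 Schwann identity genes, from counts summed over all cells. Points are the 3 SD and 2 HFD libraries and bars are diet means; S100a9 averages 6132 on HFD and Mbp 3431 on SD and 701 on HFD.

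Within the macrophages of cluster 0, Il1b, the gene of the inflammatory cytokine interleukin-1 beta, was the 1 gene of 2108 that passed, and it was lower on HFD. The test compared 53 SD cells of 2 libraries with 82 HFD cells of 2 libraries. Il1b was at 605 ± 61.1 CPM on SD (standard deviation, n = 2) and 32.9 ± 35 on HFD (n = 2), a log2 fold change of -4.01 ± 0.55 (SE; edgeR adjusted p = 0.019). Il1b was counted in 7 of the 53 SD cells and 8 of the 82 HFD cells, and 3 SD cells held 77.9% of the SD UMIs. All 29 Il1b UMIs of SD replicate 2 lay in 1 cell. Within run 1 the log2 ratio was -3.19. In run 2, SD replicate 3, below the minimum of cells, had 0 Il1b UMIs in 8 cells with 8291 UMIs, and HFD replicate 2 had 1 in 42 cells. Over all cells Il1b was instead higher on HFD, at 163 ± 148 and 826 ± 528 CPM (edgeR adjusted p = 0.943), where the neutrophil-like cells contribute. In cluster 1 its 267 UMIs lay in 5 cells, all HFD, of which 3 were neutrophil-like with 62, 77 and 38. None of these 5 cells enters the cluster 0 test. Which cell type those that were not neutrophil-like belong to was not tested.

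Lpl, Lgals3 and Cd86 lay higher on HFD in cluster 0 without passing over all genes, while Lpl and Cd86 passed when adjusted over their own list alone. Lpl, which encodes lipoprotein lipase, was at 122 ± 35.4 CPM on SD (standard deviation, n = 2) and 459 ± 167 on HFD (n = 2), a log2 fold change of 1.82 ± 0.45 (edgeR adjusted p = 0.327). The fatty acid receptor gene Cd36 was at 816 ± 57.1 and 1303 ± 313 CPM (edgeR adjusted p = 0.79), while Apoe lay lower, at 26853 ± 5491 and 22232 ± 5669. Of the 7 lipid uptake, transport and droplet genes 4 lay higher and 3 lower, and the list did not pass (camera adjusted p = 0.446; adjusted p = 0.836 with an estimated correlation). Galectin-3 (Lgals3) had a log2 fold change of 1.87 ± 0.45 and Cd86 of 1.59 ± 0.39, each with an adjusted p of 0.327. The lowest unadjusted p-values on the higher side belonged to Fgfr2 (log2 2.30 ± 0.52), the guanine exchange factor gene Vav3 (1.57 ± 0.37), the proton-sensing receptor gene Gpr65 (2.31 ± 0.55) and Lgals3. On the lower side, after Il1b, they belonged to the scavenger receptor gene Colec12 (-2.86 ± 0.67), Rnaseh2c (-2.32 ± 0.72) and Ppp1r14b (-1.73 ± 0.55). None of these 7 passed, with adjusted p-values from 0.327 to 0.613. In all, 86 genes were higher and 42 lower at an unadjusted p under 0.05, and DESeq2 also called 1 gene.

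Ribosomal protein genes were lower on HFD in cluster 0. All 79 measured members lay below SD by a median of -0.33 (camera adjusted p = 1.84e-09; adjusted p = 0.836 with an estimated correlation). Rps24 was at 7026 ± 533 CPM on SD (n = 2) and 4827 ± 70.8 on HFD (n = 2), and Rps3 at 2228 ± 53.3 and 1481 ± 309. Nuclear-encoded respiratory chain genes were below SD in 43 of 58 cases (median -0.27, camera adjusted p = 0.0417; adjusted p = 0.836 with an estimated correlation), with Cox6c at 715 ± 387 and 329 ± 16.6 CPM. No member of either list passed when adjusted over the list alone or over all genes tested. With at least 3 cells per library, which adds SD replicate 3, neither list passed. The 12 other pathway lists tested in cluster 0 did not pass, and the macrophage marker list lay lower (median -0.35 over 15 members, camera adjusted p = 0.0135; adjusted p = 0.322 with an estimated correlation).

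**Figure D3:**
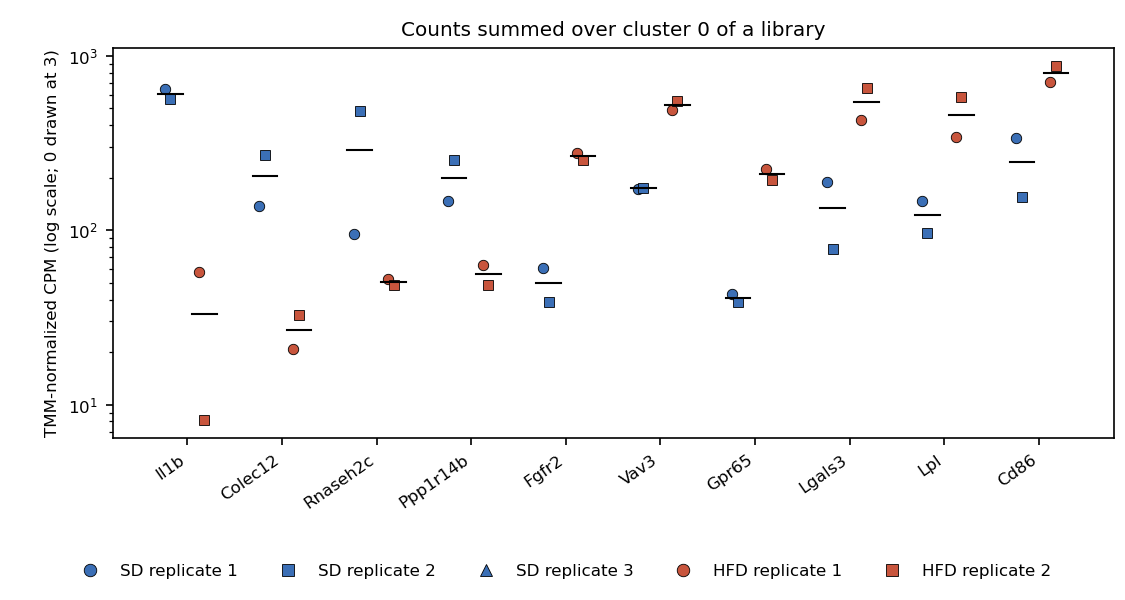
TMM-normalized CPM (vertical axis, log scale, 0 drawn at 3) of 10 genes in counts summed over cluster 0. Points are the 2 SD and 2 HFD libraries with at least 10 cells of the cluster and bars are diet means; Il1b averages 605 on SD and 32.9 on HFD, and Lpl 122 and 459.

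In cluster 2, with its high myelin gene expression, 0 of 1019 genes passed in edgeR or DESeq2, and 16 had an unadjusted p under 0.05 in edgeR. The comparison covered 35 SD and 25 HFD cells in 3 and 2 libraries. Mbp was at 6998 ± 2303 CPM on SD (standard deviation, n = 3) and 4564 ± 564 on HFD (n = 2), a log2 fold change of -0.60 ± 0.35. The log2 fold changes were -0.28 ± 0.33 for Pmp22, 0.09 ± 0.77 for S100b and 0.01 ± 0.64 for Sox10. The myelin protein list did not pass, with a median of -0.24 over 19 members (camera adjusted p = 0.0881; adjusted p = 0.593 with an estimated correlation). The synaptic adhesion gene Nlgn1 had the lowest p, at 210 ± 179 and 1814 ± 1746 CPM (log2 2.98 ± 0.74, edgeR adjusted p = 0.238). Its log2 ratio was 3.63 within run 1 and 1.83 within run 2, and it passed with the run as a term. The immediate early genes Ier2 (log2 3.16 ± 0.94) and Btg2 (1.95 ± 0.73) and the kinase gene Tesk2 (2.18 ± 0.84) followed on the higher side. On the lower side were Ndufab1 (-4.35 ± 1.52), Uqcr10 (-2.16 ± 0.81), Mir100hg (-1.45 ± 0.65) and Pnrc1 (-1.99 ± 0.98). HFD replicate 1 contributed 3 cells here, and in run 2 the ratios of Ier2 and Btg2 were -0.32 and -0.68. Ribosomal protein genes were below SD in 61 of 78 cases (median -0.34, camera adjusted p = 0.00467; adjusted p = 0.683 with an estimated correlation), a direction that turned without SD replicate 3.

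In cluster 1, 52 of 656 genes passed, 45 higher and 7 lower on HFD. The higher genes included S100a9 at 49466 ± 12547 CPM, S100a8 at 33379 ± 8066, Il1b at 6176 ± 1495 and the neutrophil chemoattractant gene Cxcl2 at 5367 ± 4480 (standard deviation, n = 2), each with 0 in the SD libraries. Mbp was lower, at 17760 ± 17051 CPM on SD (n = 3) and 1414 ± 602 on HFD (n = 2; log2 -3.62 ± 0.99, edgeR adjusted p = 0.00787). SD replicate 3, with 7 cells of this cluster, was at 37104 CPM of Mbp, and SD replicates 1 and 2 averaged 8088. The lipid transporter gene Abca8a and Lgi4, a secreted Schwann cell factor gene, were at 334 ± 204 and 300 ± 153 CPM on SD and 0 on HFD, and the choline phosphotransferase gene Chpt1 was at 780 ± 705 and 26 ± 36.8. Pmp22 (log2 -1.06 ± 0.88) and S100b (-2.44 ± 1.16) did not pass. All 17 measured myelin protein genes lay below SD (camera adjusted p = 4e-06; adjusted p = 0.764 with an estimated correlation). Antigen presentation genes lay higher in 8 of 8 cases (camera adjusted p = 0.00792; adjusted p = 0.863 with an estimated correlation) and ribosomal protein genes in 77 of 78 (camera adjusted p = 0.00137; adjusted p = 0.863 with an estimated correlation). The comparison sets deep cells of HFD replicate 1 (median 6340.5 UMIs) against shallow SD cells (medians 301 to 880). The HFD libraries held 24 cells of this cluster, among them 3 neutrophil-like cells and the haemoglobin-rich barcode. Macrophage markers were at 4981 and 4193 CPM in the HFD libraries of this cluster and at 1476, 133 and 0 in the SD libraries, and Cd74 was counted in 9 of 92 cells. Without the neutrophil-like cells 4 genes passed, 3 higher and 1 lower. The median log2 fold change of all genes was 0.42 with TMM and 0.61 with RLE scaling.

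Cluster 4 gave 0 of 327 genes past the threshold in edgeR and in DESeq2, and 4 genes at an unadjusted p under 0.05 in edgeR. It compared 13 SD and 11 HFD cells in 2 and 2 libraries. Dissociation-induced immediate early and heat shock genes lay higher on HFD in 13 of 15 cases (median 1.05, camera adjusted p = 1.45e-09; adjusted p = 0.311 with an estimated correlation). Nr4a1 was at 126 ± 34.4 CPM on SD (n = 2) and 1535 ± 104 on HFD (n = 2), Btg2 at 735 ± 401 and 4202 ± 2756, Junb at 3844 ± 756 and 12212 ± 4008, and Egr1 at 1846 ± 270 and 8221 ± 6976. Extracellular matrix genes lay lower in 12 of 13 cases (median -0.70, camera adjusted p = 0.00734; adjusted p = 0.311 with an estimated correlation), a direction that turned without SD replicate 1. The fibroblast marker list lay lower in 5 of 7 cases (median -0.70, camera adjusted p = 0.0208; adjusted p = 0.278 with an estimated correlation). The collagen genes Col3a1 and Col6a2 were at 8741 ± 22.6 and 2571 ± 1044 CPM on SD and 2621 ± 2235 and 605 ± 80.9 on HFD. Mir99ahg (log2 -1.81 ± 0.82) and Igfbp6 (-1.51 ± 0.73) completed the genes with the lowest p. Ribosomal protein genes lay higher in 47 of 75 cases (median 0.17, camera adjusted p = 0.000115; adjusted p = 0.545 with an estimated correlation), a direction that turned without HFD replicate 1. Fibroblast and endothelial genes are both expressed in this cluster, so its counts combine them.

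The diet difference was compared between clusters 0 and 2 directly, and 0 of 2257 genes passed in edgeR, with 25 at an unadjusted p under 0.05. The 5 genes with the lowest p were Pde7b, Ndufab1, Chmp4b, Arhgef11 and Ifrd1. The lowest adjusted p was 0.806, for Pde7b. DESeq2 was not run for this test.

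Macrophages of cluster 0 made up 28.6% ± 8.17 of cells on SD (standard deviation, n = 3) and 54.9% ± 21.6 on HFD (n = 2). The difference of 26.3 percentage points had the smallest p that the 10 splits can give (exact permutation p = 0.1, BH-adjusted 0.5), and both HFD libraries lay above all 3 SD libraries. It was 37.2 within run 1 and 19.6 within run 2, and 11 without HFD replicate 1. Without barcodes of the shared ending it was 24.1. Shares in run 2 include 18 such barcodes among 40 cells of SD replicate 3 and 16 among 106 of HFD replicate 2. All of these barcodes lie in cluster 3, so they enlarge the totals that the run 2 shares of the other clusters are taken over, more so in SD replicate 3. Differences within runs were not computed without them, and the size and sign of the run 2 differences of each cluster may not hold. Cluster 1 made up 31.1% ± 13.5 on SD (n = 3) and 14.6% ± 0.749 on HFD (n = 2; exact permutation p = 0.2, BH-adjusted 0.5), with differences of -23.8 within run 1 and -2.41 within run 2. Cluster 2 made up 17% ± 5.97 and 13% ± 11 (exact permutation p = 0.7), cluster 3 17.9% ± 25.6 and 10.7% ± 10.2 (p = 0.9), and cluster 4 5.38% ± 5 and 6.81% ± 0.293 (p = 0.8). Differences within run 1 and within run 2 were -12.8 and 5.75 for cluster 2, 0.407 and -29.6 for cluster 3, and -1.05 and 6.60 for cluster 4. Without barcodes of the shared ending the differences were -20.3 for cluster 1, -6.37 for cluster 2 and 1.94 for cluster 4. For cluster 3 the means were then 2.77% on SD and 3.42% on HFD, a difference of 0.651. SD replicate 3 held 47.5% of its cells in cluster 3 (exact 95% interval 31.5% to 63.9%) and none of its 40 cells in cluster 4, which allows up to 8.81% (exact 95% limit). Of its 19 cells in cluster 3, 18 were barcodes with the shared ending. Effects of O4 selection, dissociation and depth per cell on these shares were not tested.

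**Figure D4:**
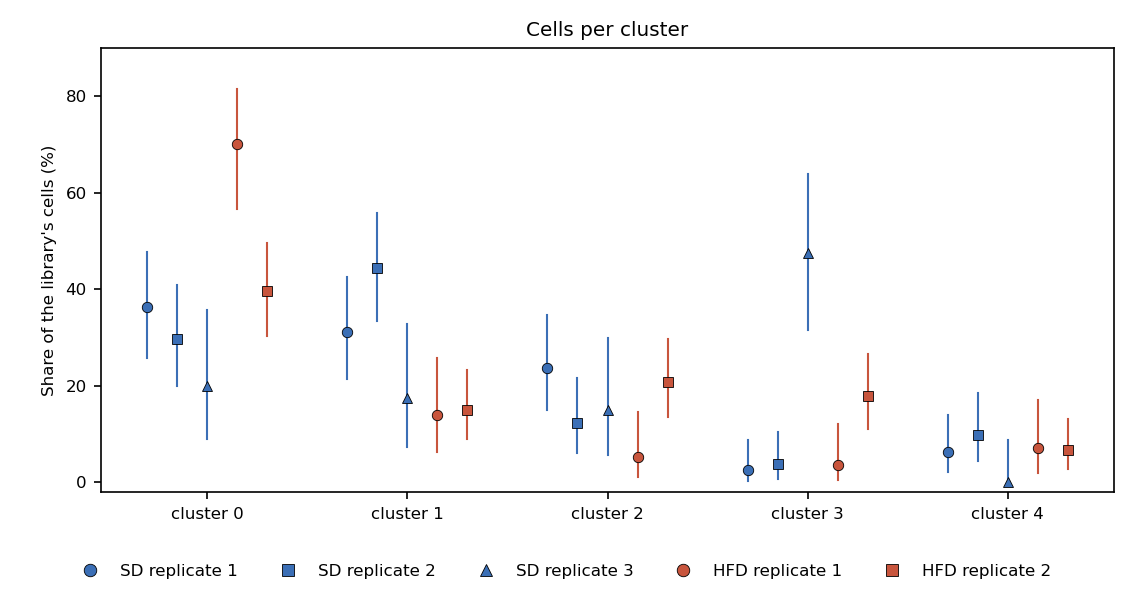
Share of each library's cells in each of the 5 clusters (vertical axis, percent), with exact 95% binomial intervals that cover counting error only. Points are the 3 SD and 2 HFD libraries. HFD replicate 1 has 70.2% of its cells in cluster 0 and SD replicate 3 has 47.5% in cluster 3. Of those 19 cells of SD replicate 3, 18 are barcodes with the shared ending.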

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

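All tests in this part were chosen after the results were seen.

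Barcodes with a shared ending were a feature that no planned comparison examined. They were included in the sums over all cells and in the cluster shares. The last 9 bases were TCCCATGGG in 36 of the 364 barcodes, and no other ending of that length occurred more than 3 times. All 36 lay in cluster 3, 80% of its cells, with 18 in SD replicate 3, 16 in HFD replicate 2 and 2 in SD replicate 2. They carried an unusual set of genes: Chl1 was counted in all 36 at 64150 CPM, against 20.9 in the other cells, and Klkb1 at 12750 against 1.75. RNA free in the suspension is argued against because 0.562% of UMIs lay in the 50 most abundant genes of the other cells, against 27.5% there. Nonmyelinating or repair Schwann cells, as intact cells, are argued against by the 11 genes that rank among the 50 most abundant in each of the 4 other clusters. These had 38 UMIs, 32 of them from 4 mitochondrial genes, where 726 were expected at the lowest rate of those clusters. An artefact of barcode or library synthesis was not tested and stays open, and the 2 libraries of run 2 hold most of these barcodes.

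The 5 genes with UMIs in the HFD libraries alone may reflect a few neutrophil-like cells. Retnlg, Slc7a11 and Stfa2l1, which did not define those cells, had 99.2% of their UMIs in them. Lower depth of the SD libraries is argued against, since at the pooled HFD rate the least abundant of the 5 genes would have given 95.3 UMIs there and gave 0. That number treats UMIs as independent draws, while all 130 UMIs of this gene, Stfa2l1, lay in 4 cells. It does not weigh how many such cells would have been sampled. Whether diet brought these cells cannot be told apart from sampling of cells, because the share of such cells per library had an exact permutation p of 0.1, the smallest 3 against 2 libraries can give. Blood left in the nerve stays open and was not tested.

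Lower Il1b in cluster 0 on HFD may rest on a few cells with many Il1b UMIs, since 3 SD cells held 77.9% of the SD total. Lower depth of the HFD cells is argued against because they held 1.80 times the UMIs of the SD cells. At the SD rate 187 Il1b UMIs were expected in them and 12 were seen, which restates the gap in CPM. Sequencing run cannot be excluded by the log2 fold change of -3.38 with the run as a term. Run 2 held HFD replicate 2 alone in this test, so that value restates the gap inside run 1. There Il1b was at 605 CPM on SD and 57.6 on HFD, a gap within a single run. That gap rests on 1 HFD library, and in run 2 Il1b had 0 UMIs in SD replicate 3 and 1 in HFD replicate 2. A diet effect on how often such cells occur stays open and was not tested. HFD cells of cluster 1 with Il1b UMIs do not enter this comparison.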

How the results depend on the processing

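Settings with the run as a term, without barcodes of the shared ending, without S100a8 and S100a9 cells, without cluster 0 and with at least 3 cells per library were added after the results were seen. Where a setting leaves 1 library in a diet, edgeR assumes it varies like the others. This holds for some left-out libraries, for clusters 1 and 2 with at least 10 cells (2 SD and 1 HFD library) and for cluster 1 without cells carrying non-Schwann markers (3 and 1). The lower level of cluster 0 Il1b kept its direction in every setting run, with log2 fold changes from -6.02 to -3.38. Its call held in each setting with at least 2 libraries per diet. Leaving out barcodes of the shared ending or S100a8 and S100a9 cells, or asking for at least 20 cells, removed no cell of this test. No setting left out the 3 SD cells that held 77.9% of the SD Il1b UMIs. Of the values of named genes, 591 of other settings kept direction and call, 28 were weaker, 17 stronger and 8 reversed, and with a library left out 302, 18, 12 and 6. Most named genes had no call to lose. Some settings also left out no cell of a cluster, so its values there could not change and count as kept. This held for barcodes of the shared ending in clusters 0, 1, 2 and 4 and for S100a8 and S100a9 cells in clusters 0, 2 and 4. It also held for at least 20 cells in cluster 0.

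Leaving out cells carrying non-Schwann markers removed 264 of the 364 cells and, over all cells, left 202 genes. It removed 45 of the 60 cells of cluster 2, with a median of 4230 UMIs, and 13 of the 45 of cluster 3, with a median of 261. In cluster 2, 38 cells held at least 2 UMIs of the fibroblast list. Deep cells meet this rule more easily, so the cells left are not a set of Schwann cells. Its marker lists hold S100a8, S100a9 and Retnlg, so that setting could not keep the calls of these genes. Over all cells 5 genes passed. The count was 9 with DESeq2, 47 with no filter on low counts, 0 without cells carrying non-Schwann markers (3 at an unadjusted p under 0.05), 57 with the run as a term, 8 without barcodes of the shared ending, 0 without S100a8 and S100a9 cells, 1 without cluster 0, and 0 to 54 with a library left out. Of the 6 lists, 0 passed with an estimated correlation, 0 with fry and 1 without cells carrying non-Schwann markers, where all cells Rps29 was -0.75 and the mean of all cells cytosolic ribosomal proteins -0.17. In cluster 0, with 1 gene, the count was 4 with no filter and 2 to 26 with a library left out. Its 2 lists became 0 with an estimated correlation, 0 with fry, 1 with the run as a term, 0 with at least 3 cells and 1 to 3 with a library left out. With at least 3 cells cluster 0 H2-DMb1 was -0.011, and cluster 0 Pmp22 ranged from -0.0078 to 1.01 with a library left out.

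In cluster 1, with 52 genes, the count was 80 at an adjusted p under 0.1, 8 with no filter, 0 without cells carrying non-Schwann markers (4 unadjusted), 4 without S100a8 and S100a9 cells, 13 with at least 10 cells and 22 to 99 with a library left out. Its 3 lists became 0 with an estimated correlation, 0 with fry, 0 without cells carrying non-Schwann markers and 1 to 3 with a library left out. In cluster 2, with 0 genes, the count was 2 with no filter, 1 with the run as a term, 3 with at least 10 cells and 0 to 4 with a library left out. Its 1 list became 0 with an estimated correlation, 0 with fry, 2 with the run as a term, 0 with at least 10 cells and 0 to 4 with a library left out. For cluster 2 Sox10 the log2 fold change was -0.0011 with RLE, -0.078 with no filter, -0.0034 with the run as a term, -0.14 with at least 10 cells and -0.36 to 0.36 with a library left out. With at least 10 cells cluster 2 Pmp22 was 0.16 and the mean of cluster 2 myelin proteins 0.10. With a library left out these were -1.21 to 0.22 for Pmp22, -0.27 to 0.50 for cluster 2 S100b, -1.41 to 0.033 for myelin proteins and -0.59 to 0.094 for cluster 2 cytosolic ribosomal proteins. In cluster 4 the count was 0 to 2 with a library left out, and its 3 lists became 0 with an estimated correlation and 0 with fry. The mean of cluster 4 extracellular matrix and basal lamina was -1.47 to 0.36 and that of cluster 4 cytosolic ribosomal proteins -0.19 to 0.74 with a library left out. The test of diet by cluster gave 0 to 1.

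With a library left out the difference in cell depth, median UMIs per cell, was -349 to 5441, that in cell depth, median genes per cell, -133 to 1294 and that in the mitochondrial percent -0.093 to 0.17. For class shares, HFD vs SD, cluster 0, the difference was -0.51 without cells carrying non-Schwann markers, and for class shares, HFD vs SD, cluster 2, it was 23.3 there and -11.8 to 3.72 with a library left out. That setting removes 140 of the 143 cells of cluster 0, so these 2 differences do not test its share. For class shares, HFD vs SD, cluster 3, it was 1.38 without those cells, 0.651 without barcodes of the shared ending and -14.9 to 7.61 with a library left out, and for cluster 4 -1.25 to 3.69.

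The diets share replicate numbers 1 and 2. No label says that a number marks a shared animal or batch, and 2 pairs are too few for the data to decide. Correlations of deviations from the diet means were 0.282 and -0.0865 for the same number and 0.282, 0.0865 and 0.235 for the same run, and with 2 HFD libraries each SD library has opposite values with the 2. With the replicate block the counts were 64 over all cells, 5 in cluster 0, 22 in cluster 1 and 2 in cluster 2, with 10 lists over all cells and 0 in cluster 2, cluster 2 S100b was -0.56, cluster 2 cytosolic ribosomal proteins 0.11, the mitochondrial difference -0.049 and the share differences 7.61 for cluster 3 and -1.25 for cluster 4. The other 9 splits of the 5 libraries gave 0 genes over all cells, and 10 splits cannot give a share under 0.05. No value could be given for clusters 0, 2 and 4 without cells carrying non-Schwann markers, for clusters 1, 2 and 4 with at least 20 cells, or for cluster 4 with at least 10.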

Other observations

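The comparison below was chosen after the results were seen. Clusters 1 and 2 both expressed myelin genes and differed in the nuclear RNA Malat1. It was lower in cluster 1 in all 5 libraries, at 4552 to 15401 CPM against 31383 to 57996 in cluster 2. Ctnna3 was also lower in cluster 1, at 0 to 967 CPM against 2218 to 5843. Gm42418 was higher in cluster 1 in all 5 libraries, at 60046 to 280787 CPM against 45685 to 66665. Erythrocyte markers made up 339403 CPM of cluster 1 in HFD replicate 1, which lowers its other CPM values.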
